A study of Caenorhabditis elegans with 2 samples.

How the data were processed

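Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on 2 biological replicates of a transgenic Caenorhabditis elegans line, per the labels. The line carries CEH-63 (sequence name C02F12.10) fused at its C terminus to EGFP and epitope tags, and a wild-type unc-119 copy in an unc-119 mutant background. Per the labels, the animals were whole starved L1 larvae of pooled sexes aged 6 hours, chromatin was sheared by sonication with a size range of 200 to 800 bp, and an anti-GFP antibody was used, although the antibody field itself reads ceh-63. Both replicates form 1 group. No second condition exists in the series, and the control library is not among its samples and was not analysed here.

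The deposited data were 4 lists of peak intervals on the ce11 assembly, the same sequence as WBcel235. Per the README text deposited with the samples, the authors called 1 list on each replicate and 1 on the alignments of both replicates together (the pooled list), each with the same control alignment, and derived a reproducible list from these 3 with an irreproducible discovery rate (IDR) threshold. The aligner, the peak caller, the read depth and the IDR threshold are not given in the sources used here. Each deposited peak has a signal value from the caller whose scale is not stated, so signal was used only to rank peaks within a list, and no signal was compared between lists. Each deposited peak also has a −log10 q-value, as the narrowPeak format defines that column, and the column for p-values was left unset. Read counts are not part of these files, so the sequencing depth of either replicate is unknown. The Wilson intervals (95%) given with shares cover only the counting of peaks, and neighbouring peaks and genes are not independent.

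The summit was taken from the offset deposited with each peak, which is the centre of the interval for every peak except the single narrow one. Peaks were annotated with the Ensembl release 115 gene models for WBcel235, leaving out pseudogenes, and a peak was assigned to every gene with an annotated start within 1000 bp of its summit. Where several peaks were assigned to a gene, the one with the highest signal stood for it. A gene with an assigned reproducible peak is called bound, which gives the position of a peak and does not show binding by CEH-63. Each summit was placed in 1 feature class (coding exon, 5′ UTR, 3′ UTR, exon of a non-coding gene, intron or intergenic). Upstream and downstream refer to the direction of transcription from the start. Coordinates are 1-based.

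Before the data were examined, the following comparisons were fixed. Replicate overlap was the share of the 479 highest-signal peaks of one replicate with a summit within 200 bp of one of the 479 highest of the other, against 1000 random draws of as many peaks from the full list of replicate 2 (one-sided permutation test). Rank agreement was Spearman's coefficient across the reproducible peaks. The share of reproducible peaks near a start was set against 10000 draws of as many peaks from the other pooled peaks (one-sided permutation test). Genes with a reproducible peak were compared with the other genes that had a pooled peak near their start by Fisher's exact test (two-sided) over 22 lists, with Benjamini-Hochberg adjustment and a threshold of 0.05. The lists were homeobox genes, nuclear hormone receptors, DVC neuron genes, pan-neuronal genes, neuropeptides, ribosomal proteins, translation factors, histones, heat shock and chaperone genes, vacuolar ATPase subunits, collagens and cuticle genes, epidermis, body wall muscle, pharynx, intestine, germline, glia, starvation and insulin pathway, molting and heterochronic genes, tRNA genes, snoRNA with snRNA genes, and microRNA genes. In all, 8 symbols written by hand into the lists did not match the annotation (daf-21, ami-1 and 6 entries for microRNAs, 1 of them in 2 lists), and those entries were not counted. The homeodomain core TAATTA was counted within 50 bp of summits and of positions 500 bp to either side (exact binomial test, two-sided), and all 2080 words of 6 bases were searched by Fisher's exact test. The X share was tested against the pooled list by Fisher's exact test (two-sided). Peaks within 20 kb of ceh-63 and unc-119 were counted and set beside 10000 random gene-centred windows.

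Named genes followed a rule fixed at the same time: the nearest gene of each of the 20 reproducible peaks with the highest signal, up to 4 members with the highest signal of each list past the threshold or with at least 2 bound members, ceh-63, unc-119, ceh-14 and mbr-1 in any case, and genes whose peak ranked in the top 20 of one replicate and beyond rank 479 of the other. Genes sharing a peak with such a member are named with it. The report also names rpl-27, rps-20, crt-1, Y48B6A.1, F26D10.24 and F46C8.15, which lie outside this rule and were chosen after their values were seen. The tests by feature class, by chromosome group, of X among the top 20 peaks and of base composition, and the overlap by rank, were chosen after the data were seen.

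The tests were tested on simulated data, with 20 sets of 479 peaks drawn from the pooled list. With a doubled weight on peaks near a start, or on X, the promoter and X tests called 20 of 20 sets. With a 5-fold weight on peaks near snoRNA and snRNA genes, that list was called in 20 of 20 sets, and with TAATTA planted in 20% of peaks the motif test called 20 of 20 sets. Smaller excesses of TAATTA were not planted. Summits outside the reproducible set were 39.0% GC, against 44.4% within it, so the power for a smaller excess in the reproducible peaks is unknown. Without any planted difference, the promoter and motif tests called 0 of 20 sets, the X test 1 of 20, the snoRNA and snRNA list 1 of 20, and any list at all 3 of 20. Alternatives covered stricter peak sets, each replicate alone, other distances, other backgrounds, other windows and other definitions of overlap. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.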

Results

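CEH-63 is a homeodomain protein known from the DVC interneuron of C. elegans. Its binding was profiled by ChIP-seq in starved L1 larvae that carry a GFP-tagged copy of the gene, in 2 biological replicates. The replicate lists and the pooled list held 30000 peaks each, a relaxed set in which most peaks are weak. The median −log10 q was 0.0932 in replicate 1, 0.0479 in replicate 2 and 0.0376 in the pooled list. A q of 0.05 or less was reached by 172 peaks in replicate 1, 191 in replicate 2 and 194 in the pooled list. The reproducible list held 479 peaks. All 479 were exactly the 479 highest-signal peaks of the pooled list, with signal values from 486 down to 111.6 (median 132), and 194 of them had a q of 0.05 or less. Peak width was set by the list (356 bp in replicate 1, 380 bp in replicate 2 and 370 bp in the pooled list), apart from 1 pooled peak of 107 bp. The read depth is unknown.

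The first question was how far the replicates found the same sites. The strongest sites recurred: the peaks at rpl-3, which encodes a ribosomal protein of the large subunit, and at ceh-63 itself ranked 1 and 2 in replicate 1 and 3 and 2 in replicate 2. Of the 20 highest-signal peaks of replicate 1, 15 (75%) had a summit within 200 bp of one of the 20 highest of replicate 2. Among the top 100, 64 (64%) matched, and among the top 479, 208 matched, or 43.4% (95% Wilson interval 39.1 to 47.9). In the reverse direction, 209 of the top 479 of replicate 2 matched (43.6%). Random draws from the list of replicate 2 gave 1.5% on average and 3.76% at most, and the one-sided permutation p of 0.001 was the smallest that 1000 draws can give. Over all 30000 peaks 43.0% matched, against 12.2% after replicate 2 had been shifted by 10 kb. Both lists were called with the same control alignment, so part of the overlap may come from that control.

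Within the reproducible set, ranks differed between the replicates. Across the 473 reproducible peaks with a counterpart in both replicates, Spearman's coefficient of the ranks was 0.292, a value across peaks, which are not independent replicates. These peaks were also those with the highest pooled signal, which restricts the range of ranks and can lower the coefficient, so it does not measure agreement over the whole lists. Of the 479 reproducible peaks, 208 ranked within the top 479 of both replicates, 224 within that of 1 replicate, and 47 within neither. A replicate peak could be matched to more than 1 reproducible peak, as for the peaks of rank 25 and 203 at sls-2.1. These counts and the coefficient therefore do not rest on separate matches throughout. Within 200 bp, 5 reproducible peaks had no counterpart in replicate 2 and 1 had none in replicate 1. For 4 of the 5, replicate 2 had a peak just beyond that distance: 211 bp away at lgg-1, an autophagy gene (rank 303 in replicate 2), 232 bp away at icl-1, which encodes a glyoxylate cycle enzyme (rank 421), 264 bp away at the chaperone gene hsp-90 (rank 916), and 220 bp away near Y48B6A.1 (rank 259). The other was in a coding exon of the calreticulin gene crt-1, where the nearest replicate 2 peak was 883 bp away. The peak missing from replicate 1 was on IV at 17281220 to 17281589, with F26D10.24 as its nearest start, and ranked 91 in replicate 2. A single peak ranked in the top 20 of one replicate and beyond rank 479 in the other. It lay on chromosome I at 4172191 to 4172560, intergenic, 70 bp upstream of the non-coding gene R12E2.18, with rank 14914 in replicate 1 and rank 11 in replicate 2. Its summit is 210 bp from that of the stronger peak at the spliced leader gene sls-2.4, which also had rank 11 in replicate 2, so a single replicate 2 peak was matched to both.

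**Figure D1:**
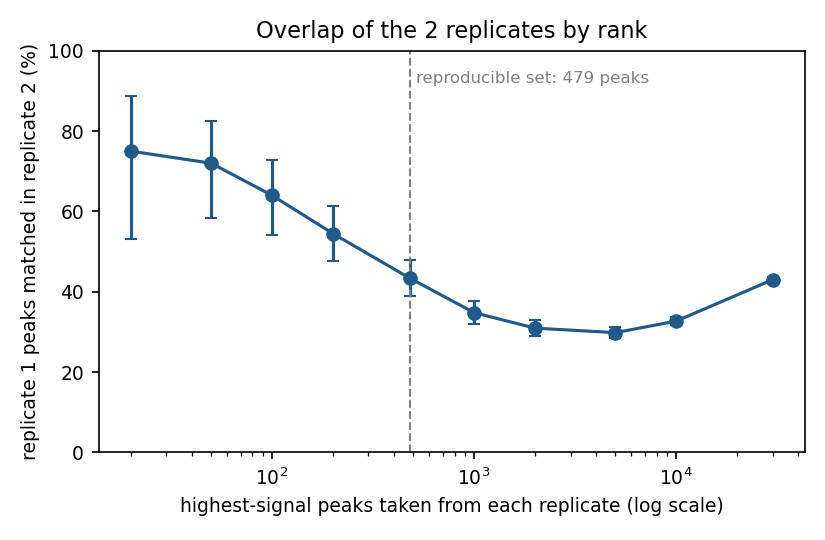
Share of the highest-signal peaks of replicate 1 with a summit within 200 bp of a peak among as many highest-signal peaks of replicate 2 (y axis, percent), against the number of peaks taken from each list (x axis, log scale), with 95% Wilson intervals as error bars and a dashed line at the size of the reproducible set. The share was 75% at 20 peaks, 43.4% at 479 and 29.8% at 5000.

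The 20 reproducible peaks with the highest signal fell near the starts of ribosomal protein, spliced leader and other genes, at ceh-63, and at sites far from starts on the X chromosome. A start lay within 1000 bp of 12 of them. The top peak was on chromosome III at 3867517 to 3867623, 288 bp upstream of rpl-3 (signal 486), and was also the single narrow peak of 107 bp. The second was on X at 3673599 to 3673968, in the 5′ UTR of ceh-63 (WBGene00045215), with a signal of 461. The next autosomal peaks were at F56G4.6 on I (11374261 to 11374630, intergenic, signal 423), tasp-1 on III (10759098 to 10759467, 24 bp upstream, signal 407), and cux-7 on III (7520690 to 7521059, 30 bp upstream, signal 359). Those at rpl-35 on III (signal 350), sls-2.4 on I (signal 342), vps-51 on I (5807294 to 5807663, 188 bp from the start, signal 330) and the small RNA gene F59C6.15 on I (signal 313) followed. On X, the other peaks near a start were at nspc-17 (14525708 to 14526077, 712 bp upstream, signal 364), the non-coding gene C18A11.13 (8036194 to 8036563, 295 bp from the start, signal 347) and tag-52 (3678685 to 3679054, 313 bp upstream, signal 322). All of these ranked within the top 50 of each replicate.

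The other 8 peaks of the top 20 had no annotated start within 1000 bp, and 7 of them were on X. The strongest was intergenic at X 13700661 to 13701030 (signal 376), with the nearest start, that of the non-coding gene K02D3.5, 3058 bp away. The others on X were at 11094004 to 11094373 (signal 361, nearest start W02H3.t1), 806482 to 806851 (signal 356, nearest start gtr-1), 6296407 to 6296776 (signal 332, in an intron, nearest start cest-16), 5429329 to 5429698 (signal 329, in a coding exon, nearest start C41A3.6), 16681919 to 16682288 (signal 309, nearest start F22H10.2) and 11937390 to 11937759 (signal 308, nearest start F55G7.5). The autosomal one was on V at 14055050 to 14055419 (signal 325), 2605 bp from the start of F58D12.3.

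Reproducible peaks lay near annotated starts more often than weaker peaks did. A start was within 1000 bp of 326 of 479 summits, or 68.1% (95% Wilson interval 63.8 to 72.1), against 56.1% of the 29508 other pooled peaks and 51.0% of random positions. The highest share in 10000 draws from the other pooled peaks was 64.3%, and the one-sided permutation p of 0.0001 was the smallest that these draws can give. By feature, 255 summits (53.2%) were intergenic, against 29.995% of the other pooled peaks (odds ratio 2.66, adjusted Fisher's exact p = 6.1e-25). Exons of non-coding genes held 37 summits (7.72% against 2.08%, odds ratio 3.94, adjusted exact p = 6.98e-11). Coding exons held 67 (14% against 33.7%, odds ratio 0.321, adjusted exact p = 9.59e-22) and introns 21.7% of summits (against 29.7%, odds ratio 0.657, adjusted exact p = 0.00018). In 3′ UTRs there were 5 summits (1.04% against 2.87%, adjusted exact p = 0.0144), and the 11 in 5′ UTRs did not differ past the threshold (2.3% against 1.71%, adjusted exact p = 0.29).

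Ribosomal protein, heat shock and chaperone, snoRNA with snRNA, tRNA and microRNA genes had a reproducible peak more often than the other genes. In total, 576 of 21831 genes with a pooled peak near their start had a reproducible one (2.64%), and 5 of the 22 lists passed the threshold, all with a higher share. These 21831 genes, of all types except pseudogenes and with piRNA genes among them, are the background. The members of each list are counted only within it, not among all annotated members. The ribosomal protein genes had 15 of 68 members bound, that is, with a reproducible peak near a start (22.1%, odds ratio 10.7, adjusted exact p = 2.34e-09). The strongest peaks of these genes were 15 separate ones, none of them on X. Of these, 14 had their summit upstream of the start, between 27 and 571 bp, the exception being rpl-27. After rpl-3 and rpl-35 (III, 7854499 to 7854868, 450 bp upstream), the strongest were at rpl-20 (IV, 4749883 to 4750252, signal 303, 290 bp upstream) and rpl-15 (IV, 654752 to 655121, signal 244, 361 bp upstream). The rpl-20 peak lay closer to the start of Y17G9B.5 (172 bp). Heat shock and chaperone genes had 6 of 41 members bound (14.6%, odds ratio 6.38, adjusted exact p = 0.00371). They were led by hsp-90 (V, 14685597 to 14685966, signal 292), the chaperonin subunit gene cct-1 (II, 8185005 to 8185374, signal 219), the mitochondrial chaperonin gene hsp-60 (III, 1618987 to 1619356, signal 191) and the Hsp70 gene hsp-1 (IV, 17278398 to 17278767, signal 180). Each of these peaks lay closer to the start of another gene: in the same order, C47E8.4 (297 bp), mig-5 (167 bp), Y22D7AL.10 (243 bp) and the non-coding gene F26D10.23 (170 bp).

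Among the non-coding genes, 33 of the 300 snoRNA and snRNA genes in the background (475 are annotated) were bound (11%, odds ratio 4.78, adjusted exact p = 1.04e-10). The strongest peaks of these genes were 27 separate ones. The members with the strongest peaks were sls-2.4 (I, 4171981 to 4172350, 40 bp upstream, signal 342), F59C6.15 (I, 10517036 to 10517405, 71 bp upstream, signal 313), sls-2.1 (II, 5844659 to 5845028, 21 bp upstream, signal 286), and sls-2.2 with sls-2.3, which share a peak (II, 5543511 to 5543880, signal 277). The sls-2 genes encode the SL2 RNA that is trans-spliced to downstream messages of operons. The tRNA genes had 22 of 378 members bound (5.82%, odds ratio 2.33, adjusted exact p = 0.00371). With only the strongest peak of each gene counted, 8 of their 17 separate peaks were on X. The share of all tRNA genes that lie on X was not counted, so these 8 cannot be called an excess. The strongest were C18A11.t2 (X, 8036194 to 8036563, the peak also assigned to C18A11.13), then M02F4.t1 and M02F4.t2 (X, 3035949 to 3036318, signal 164) and the pair C53C7.t1 and C53C7.t2 (X, 13046284 to 13046653, signal 150). Of the microRNA genes 11 of 139 were bound (7.91%, odds ratio 3.21, adjusted exact p = 0.00514). Their strongest peaks were 8 separate ones, with 1 of them (X, 13145071 to 13145440) assigned to 4 of the 11 genes. The bound microRNA genes were led by cel-mir-52 (IV, 14033818 to 14034187, 5 bp upstream, signal 261), cel-mir-2 (signal 142), cel-mir-354 (signal 139, a peak shared with rps-20) and cel-mir-90 (signal 120). The tRNA and microRNA lists no longer passed among the strongest 239 peaks (adjusted Fisher's exact p = 0.701 and 0.761) or with replicate 2 alone (0.0567 and 0.742). With only the nearest gene of each peak counted, the tRNA, microRNA and heat shock lists no longer passed (adjusted exact p = 0.226, 0.51 and 0.48). Ribosomal protein genes still passed there, with 6 of 45 members (odds ratio 6.36, adjusted exact p = 0.00739). With starts within 2000 bp 9 lists passed, among them the DVC, pan-neuronal, translation factor and histone lists. The DVC list includes ceh-63 itself, whose locus the transgene carries, and it was not tested at this distance without ceh-63. A reproducible peak 1888 bp from the start of ceh-14, another DVC gene, also comes within this distance, though it lies closer to another start.

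**Figure D2:**
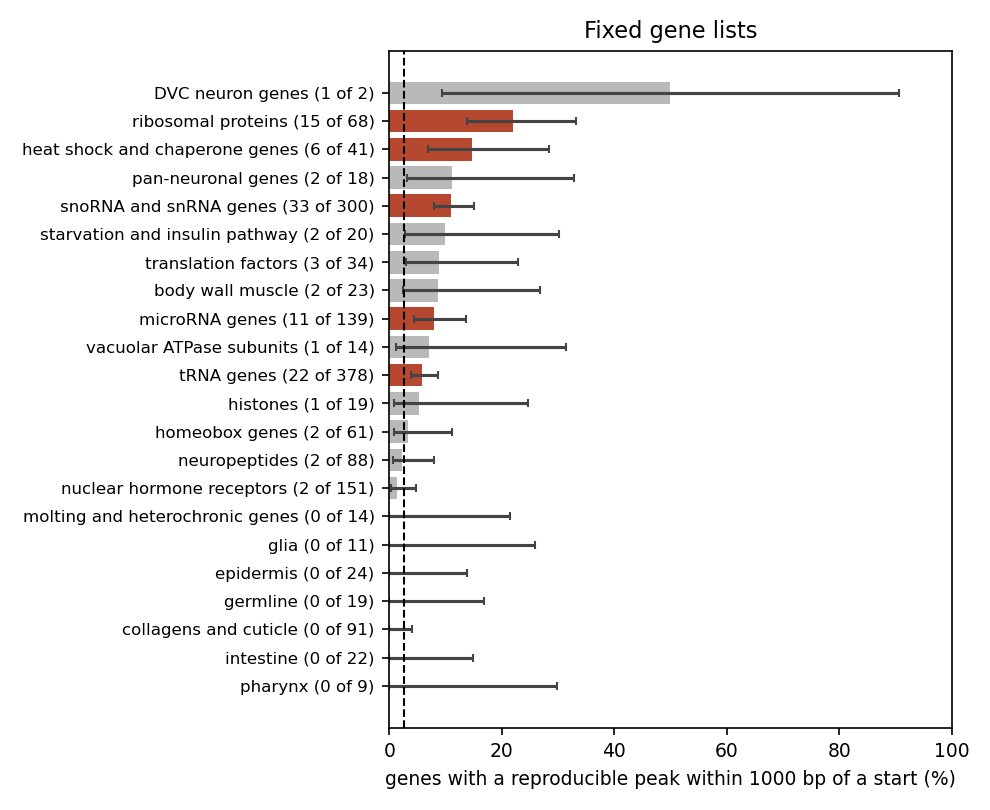
Percent of genes with a reproducible peak within 1000 bp of a start (x axis) for each fixed gene list (y axis), with 95% Wilson intervals as error bars, lists past an adjusted p of 0.05 in red, and the 2.64% of all genes in the background as a dashed line. Only list members with a pooled peak near a start are counted. Of the lists in red, tRNA genes have 5.82% and ribosomal proteins 22.1%, while the DVC bar is 1 of 2 genes.

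The remaining 17 lists did not pass the threshold, and most of them had few members in the background, so a failed test does not show that they differ from the lists that passed. Of the 2 DVC neuron genes in the background, 1 was bound, and it was ceh-63 itself (adjusted exact p = 0.188). Pan-neuronal genes had 2 of 18 bound, the kinesin gene unc-104 (signal 143) and ida-1 (signal 129), with an odds ratio of 4.63 and an adjusted exact p of 0.221. Homeobox genes had 2 of 61 bound, ceh-63 and ceh-38 (signal 186), with an adjusted exact p of 0.992. Neuropeptide genes had 2 of 88 bound, nlp-4 (the peak also assigned to F59C6.15) and ins-39 (signal 236), with an adjusted exact p of 1. Nuclear hormone receptors had 2 of 151 bound, nhr-40 (signal 114) and nhr-1 (signal 113), with an adjusted exact p of 0.7. Translation factors had 3 of 34 bound (eif-3.B, eef-1A.1 and eif-2alpha, adjusted exact p = 0.188). The body wall muscle list had 2 of 23 bound (cpn-3 and act-4, adjusted exact p = 0.269) and the starvation and insulin list 2 of 20 (lgg-1 and icl-1, adjusted exact p = 0.236). Histones had 1 of 19 bound (adjusted exact p = 0.674) and vacuolar ATPase subunits 1 of 14 (adjusted exact p = 0.573). No reproducible peak was assigned to the 91 collagen and cuticle genes in the background, of 179 annotated (adjusted exact p = 0.36), which allows a share of up to 3.3%. None was assigned to the background members of the lists for epidermis (24 genes), intestine (22), germline (19), molting and heterochronic genes (14), glia (11) and pharynx (9), each with an adjusted exact p of 1. In that order, a count of 0 allows shares of up to 12.5%, 13.6%, 15.8%, 21.4%, 27.3% and 33.3%, so a share like the 2.64% of all genes could not be told from 0 in any of these lists.

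Of the genes known to act with ceh-63 in the DVC neuron, ceh-14 and mbr-1 had no reproducible peak within 1000 bp of a start. The reproducible peak nearest to ceh-14 (WBGene00000438, X 7527769 to 7532732) was 1888 bp upstream of the gene, at X 7534435 to 7534804, and ranked 143 (rank 306 in replicate 1 and 176 in replicate 2). Its nearest start was that of the non-coding gene F46C8.15, 65 bp away. The nearest reproducible peak to mbr-1 (WBGene00011315, X 10719548 to 10722054) was 150834 bp away.

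The transgene carries ceh-63 and unc-119, so the neighbourhood of each gene was examined for an excess of peaks. Around ceh-63, the 40 kb window held 32 pooled peaks, where random gene-centred windows had a median of 12 and 0.07% of them held as many. It held 27 peaks in replicate 1 and 29 in replicate 2. Of the reproducible peaks, 5 lay in this window, with ranks 2, 17, 93, 162 and 253, against a median of 0 in random windows (0.06% held as many). They included the ceh-63 5′ UTR peak and a pair of peaks at tag-52. A further reproducible peak, of rank 51 at X 3694215 to 3694584, lay just outside this window. It was kept where the peaks within 20 kb of ceh-63 were left out. Around unc-119 (WBGene00006843, III 10902641 to 10908935), the window held 16 pooled peaks, as many as in 18.9% of random windows, and 0 reproducible peaks. The replicates fell on either side of the random median there, with 17 peaks in replicate 1 and 10 in replicate 2.

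**Figure D3:**
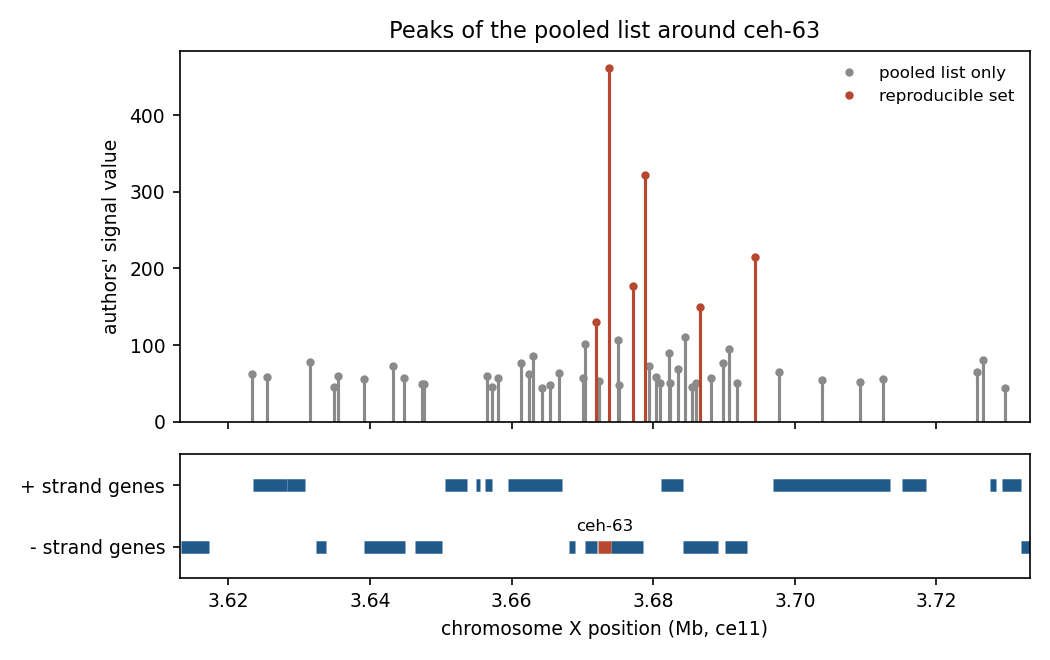
Peaks of the pooled list around ceh-63, with the position on chromosome X in Mb on the x axis and the authors' signal value on the y axis of the upper panel, reproducible peaks in red and others in grey, and protein-coding genes by strand in the lower panel. The ceh-63 5′ UTR peak has a signal of 461 and the tag-52 promoter peak 322.

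The X chromosome held 103 of the 479 reproducible peaks, or 21.5% (95% Wilson interval 18.1 to 25.4), against 17.3% of the pooled list (odds ratio 1.31, Fisher's exact p = 0.0208). Among the 20 strongest, 11 were on X (55%), against 92 of the other 459 (20.04%, odds ratio 4.88, Fisher's exact p = 0.000823). These 11 include the peaks at ceh-63 and tag-52, both within 20 kb of ceh-63, and this test was not repeated without them. Chromosome III held 100 peaks (20.9% against 15.1% of the pooled list), I held 74 (15.4% against 15.9%), II held 62 (12.9% against 15.3%), IV held 58 (12.1% against 16.6%) and V held 82 (17.1% against 19.7%). The shares of these other chromosomes were not tested, so a raised share cannot be called particular to X. The pooled list in these comparisons includes the 479 reproducible peaks. On the autosomes, 264 of 376 peaks (70.2%) were within 1000 bp of a start, against 56.6% of the other pooled peaks there (odds ratio 1.81, adjusted Fisher's exact p = 1.51e-07). On X the share was 62 of 103 (60.2% against 53.6%, odds ratio 1.31, adjusted exact p = 0.195), and the difference between X and the autosomes did not pass the threshold (Fisher's exact p = 0.0571). The X share of all reproducible peaks did not pass among the strongest 239 peaks (Fisher's exact p = 0.104), with replicate 1 alone (p = 0.0779), or without the peaks within 20 kb of ceh-63 (p = 0.0585), an alternative chosen after the data were seen.

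**Figure D4:**
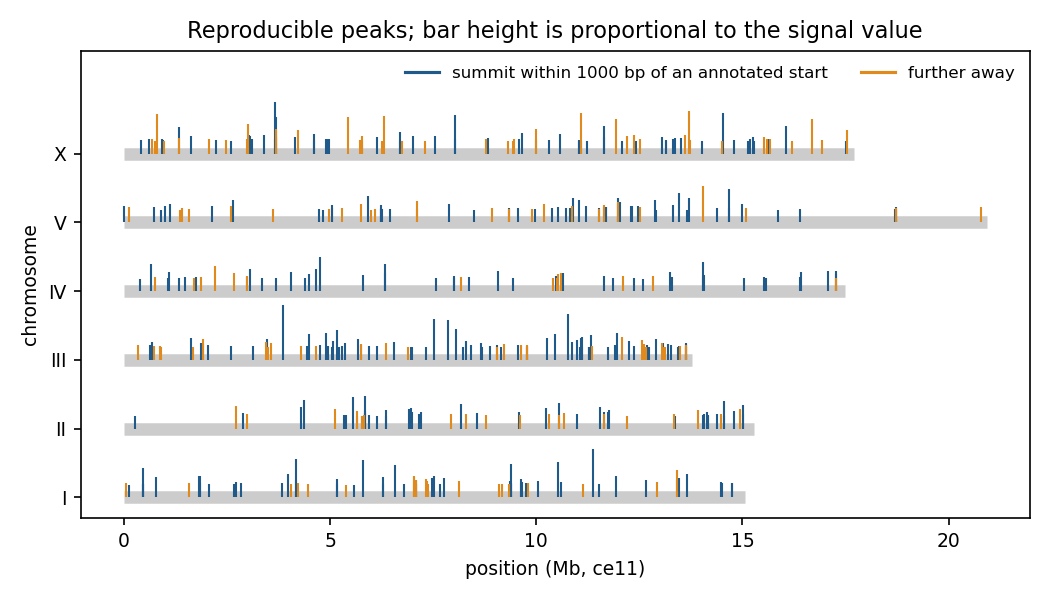
Position of each reproducible peak in Mb (x axis) along the chromosomes (y axis), as a vertical bar whose height is proportional to its signal value, blue where a start lies within 1000 bp of the summit and orange where none does. X holds 41 orange bars, among them 7 of the 20 strongest peaks.

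CEH-63 has a homeodomain, and the core bound by many homeodomains is TAATTA. In counts not corrected for base composition, it was not more frequent at summits than beside them. It was found within 50 bp of the summit at 25 of 479 peaks, or 5.22% (95% Wilson interval 3.56 to 7.59), against 6.47% at 500 bp to the left (exact binomial p = 0.504) and 5.85% to the right (exact binomial p = 0.775). In the search of all words of 6 bases, 317 passed an adjusted p of 0.05, 195 more frequent at summits and 122 less. The words with the smallest p among those more frequent at summits were CCTCTC (12.3% of summits against 3.24% of flanks, odds ratio 4.20, adjusted exact p = 6.4e-08), CGCGCA (9.81% against 2.09%, odds ratio 5.10, adjusted exact p = 9.64e-08), CCTGCG (5.01% against 0.209%, odds ratio 25.2, adjusted exact p = 9.64e-08), GCGCGC (6.68% against 0.835%, odds ratio 8.50) and GAGAGA (14.4% against 4.91%, odds ratio 3.26). Of the 48 words that contain TAAT or its reverse complement, a count chosen after the data were seen, 11 passed, with 10 less frequent at summits and 1, ATTAGC, more frequent (5.22% against 2.3%, odds ratio 2.34, adjusted exact p = 0.0344). The base composition differed as well: windows at summits were 44.4% GC (SD 8.45 over 479 peaks) and flanks 36.4%, while the other pooled peaks had 39.0% and 35.7%. A word made only of A and T is less likely in the more GC-rich summit windows, and a GC-rich word more likely. The comparison with flanks does not correct for this. It therefore cannot show whether TAATTA, the words with TAAT or the GC-rich words differ beyond base composition.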

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

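One alternative for the promoter share, gene lists, motif and X share (leaving out the reproducible peaks within 20 kb of ceh-63), and another for the gene lists (leaving out snoRNA and snRNA genes within 2000 bp of a ribosomal protein gene start), were chosen after the data were seen. The promoter share, the replicate overlap and the peak count around ceh-63 kept their direction, and those with a test their side of the threshold, under each alternative run. The promoter share was 56.6% with a start within 500 bp and 85.0% within 2000 bp, and 69.1 to 70.4% with either replicate alone. These shares count starts of all gene types except pseudogenes. With protein-coding starts only, the promoter share was 52.6%, against 44.4% of the other pooled peaks. The peak count around ceh-63 was 27 to 29 with either replicate alone. The number of gene lists past the threshold was 5, against 3 among the strongest 239 peaks, 9 with a start within 2000 bp (DVC, pan-neuronal, translation factor and histone lists were added), 2 with the nearest gene only (ribosomal proteins and snoRNA with snRNA genes) and 3 to 5 with either replicate alone. The DVC list includes ceh-63 itself, and at 2000 bp it was not tested without that gene. The odds ratio of ribosomal proteins stayed between 6.36 and 17.9, and that of snoRNA and snRNA genes between 3.41 and 6.01, past the threshold each time. It was 3.78 without the snoRNA and snRNA genes near ribosomal protein genes. The lists for tRNA and microRNA genes lost the threshold in 3 settings each and that for heat shock genes in 1. The X share was 21.3% among the strongest 239 peaks (Fisher's exact p = 0.104), 20.7% without the peaks near ceh-63 (p = 0.0585) and 20.5 to 21.3% with either replicate alone, and did not pass with replicate 1 alone (p = 0.0779). The TAATTA share was 6.28% among the strongest 239 peaks, above the flanks' 5.23%, and 3.97 to 5.85% with either replicate alone. The shorter core TAAT was at 50.1% of summits, below the flanks' 62.9%, past the threshold, without correction for the higher GC content of summits. Around unc-119 the counts with either replicate alone were 10 to 17, on both sides of the random median of 12, and other window sizes gave 7 (random median 6, windows of 10 kb to each side) and 31 (random median 24, windows of 40 kb to each side). The rank coefficient was 0.399 among the strongest 239 peaks. The cause of these shifts was not tested. The set of as many highest-signal pooled peaks is identical to the reproducible set and tests nothing. No paired analysis was possible because the series holds only 1 group. Without read counts, the effect of depth on these lists could not be examined.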

Other observations

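The counts for the SL2 genes and dense stretches and the tests over all of X were chosen after the results were seen. The genes named in the next 2 paragraphs outside the fixed rule were chosen in the same way.

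The genes for the spliced leader RNA SL2 were looked at as a family because some lay high in the list, and their ranks were not tested against those of other RNA genes. Of 18 annotated sls-2 genes, 14 had a pooled peak near their start and 6 a reproducible one. The strongest peaks of these genes were 5 separate ones, with a best rank of 12 and a median rank over the genes of 26. Further reproducible peaks near the same genes, such as that of rank 203 at sls-2.1, were not counted. Besides sls-2.1 to sls-2.4, the genes were sls-2.15 (rank 74) and sls-2.8 (rank 109). The 576 genes with a reproducible peak near a start comprised 331 protein-coding genes, 149 genes annotated as ncRNA, 26 piRNA, 25 snoRNA, 22 tRNA, 11 microRNA and 8 snRNA genes, 2 lincRNA genes and 2 antisense genes.

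The strong X peak at 8036194 to 8036563 has xol-1, the switch gene of sex determination and dosage compensation, as its nearest protein-coding gene and lies 4934 bp upstream of its start. On I, the peak of rank 14 lies between vps-51 and lin-35, the worm retinoblastoma homologue. The densest 20 kb stretch of the pooled list was on II at 10540001 to 10560000, over mnk-1, with 26 pooled peaks (25 in replicate 1, 21 in replicate 2), where the median stretch held 6 and the 99th percentile was 14. Only 1 of the 26 was reproducible.

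The first pattern was the set of 41 reproducible X peaks more than 1000 bp from any start. A candidate explanation is that they mark elements with the motif TCGCGCAGGGAG, a 12-bp word known from the sites that recruit the dosage compensation complex to X. A match with at most 2 mismatches within 150 bp of the summit was present at 9 of 41 (22%, 95% Wilson interval 12.0 to 36.7) and at 11 of 2365 other pooled X peaks as far from a start (odds ratio 60.2, Fisher's exact p = 7.02e-12). The motif may therefore account for part of the set, but base composition was not matched. Over all chromosomes, reproducible summits were 44.4% GC and other pooled summits 39.0%. The words CGCGCA and CCTGCG, from the search of all 479 summits, lie within this motif in either orientation. The motif test is therefore not independent of that search. Exactly repeated sequence is argued against, since the median share of 36-mers within 100 bp of the summits that recur in the genome was 0%. Diverged repeats were not examined. A TAATTA core at the summit stays open, with 9.76% of the peaks (4 of 41) against 0% of the left flanks (exact binomial p = 0.125, the smallest that 4 peaks allow) and 4.88% of the right flanks (exact binomial p = 0.688). Whether CEH-63 itself binds there, or whether these sites are recovered with any tagged protein, was not tested, because no other tagged protein or control library was analysed here.

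Over all of X, 15 of 103 reproducible peaks had such a match, against 3 of 376 on the autosomes (odds ratio 21.2, Fisher's exact p = 1.88e-08). The X peaks with a match had a median rank of 20 and those without one of 259 (permutation p = 2e-05, two-sided, the smallest that 100000 resamples can give), and 8 of the 11 X peaks in the top 20 had one.

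The second pattern was the peaks at ribosomal protein genes. Signal spread over the annotated bodies of strongly transcribed genes is argued against as the source of each gene's strongest peak. The summit of that peak lay between the start and the end of the gene at 0 of 15 genes, or 0% (95% Wilson interval 0 to 20.4). Further peaks at these genes, and transcription upstream of the annotated starts, were not examined. Capture of open promoters of active genes without regard to the tagged protein was not tested, since it needs a control or another tagged protein, and it stays open beside binding by CEH-63.

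The third pattern was the cluster of peaks around ceh-63, for which extra copies of the locus in the transgene are a candidate explanation. The 40 kb window held 32 pooled peaks against a random median of 12, as that explanation needs, but their median rank was 8899.5, not within the top 3000 that it was set to need. Around unc-119, also on the transgene, there were 16 pooled peaks with a median rank of 15411, as many as in 18.9% of random windows, and 0 reproducible peaks, so there was no clear excess to explain. At ceh-63, extra copies and local binding cannot be told apart from these lists, because the copy number and the extent of the inserted DNA are not given in the sources used here. No biological explanation was tested for this cluster.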
